A study of Mus musculus with 670 samples.

How the data were processed

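Single cells sorted from mouse long bones into wells of 7 plates were sequenced by SmartSeq2, and 1 table with 1 column per cell was used. Its values are RSEM expected counts per gene symbol, made by the submitters and used as deposited. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.18, aligned with STAR 2.4 to GRCm38.p6 and counted with RSEM 1.2.21. The annotation release and any earlier filter are not stated. The table holds 55604 gene rows and 92 rows of ERCC spike-ins, and 14.8% of its values above 0 are not whole numbers, so values were rounded to whole numbers first. Spike-in rows were kept out of all totals. There were 28 rows named by a number of 5 digits, as a spreadsheet date leaves behind; they were not renamed and none is reported. Columns were joined to samples by plate, well, age and index sequences, and 1 column that matched no sample was not used. The columns of plate 4 carry another name prefix than the titles of its samples, and the join did not use the prefix. Genes were matched by symbol to GENCODE annotation of GRCm38 for coordinates and gene types.

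Ages were taken from the sample labels. The labels give 7 plates in 5 batches. The plates of 2 months carry batches 4, 5 and 1, those of 24 months batches 3, 2 and 3, and the plate of postnatal day 3 batch 3. No label states an animal. The titles carry codes such as M1 and M3 whose meaning is not given, and the same code occurs at postnatal day 3 and 24 months, so codes were not read as animals. An age is therefore 1 sample and no test across samples was made. Counts of passing cells were summed per plate and divided by the plate's total to give CPM, and an age's value is the mean of its plates with equal weight. The fold is the log2 ratio of these means with 1 CPM added to each. A gene counted as different when the higher age had at least 10 CPM, the means differed at least 2-fold and no plate of one age overlapped the range of the other. Where an age had 0 reads of a gene, levels are given in place of a fold, and list medians are also given with such genes at the level 3 reads would give. Shares of cells carry exact 95% binomial intervals, and a count of 0 is given with the share that 3 cells would make.

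A cell passed with at least 1000 genes, at least 50000 gene reads and under 20% mitochondrially encoded reads. Of the wells, 433 did not pass and were left out of the comparisons. Median gene reads of passing cells were 1100490 at postnatal day 3, 677688 at 2 months and 2733860 at 24 months. With 15 cells at 24 months, a gene found in 0 cells can be present in up to 20% of them, against 4.41% at postnatal day 3 and 1.95% at 2 months. For detection in cells, genes per cell, cell cycle genes and similarity, each cell was thinned at random to 50000 reads, except for Xist and Y-linked genes, where all reads were used.

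Differences were checked on simulated data. Plates of the real sizes were drawn from the 2-month cells 20 times, with and without 200 genes changed 4-fold or 16-fold, and the same rule was applied. For 24 against 2 months, the rule recovered 8.5% of genes made 4-fold higher and 38.6% of those made 4-fold lower. For postnatal day 3 against 2 months these shares were 71.1% and 47.6%, and for 24 months against postnatal day 3 they were 13.3% and 66.4%. The calls made with no difference present are given beside each count. The limit of detection in at least 30% of cells was added after these results were seen.

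Fixed gene lists were compared by the number of genes meeting the rule, the median log2 fold of genes with at least 5 CPM at either age, and its percentile among 10000 random lists matched in size and in 20 bins of expression. Genes reported by name were fixed in advance (Csf1, Tnfsf11, Tnfrsf11b, Runx2, Sox9, Pparg, Cxcl12, Lepr, Cd200 and Itgav) or had the 8 highest or lowest folds in a comparison. The latter had to have at least 20 CPM, be detected in at least 10% of cells of the higher age, and lie at least 1.5 times apart between the nearest plates. Of the genes with the highest folds, 1 is not reported here. Others are members of the fixed lists, and widely known genes among them were preferred. Reads of near-identical genes (Bglap and Bglap2, the Serpina1 genes, class I H2 genes) cannot be assigned with certainty.

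Clusters were made from passing cells with scanpy 1.11.5 and igraph 0.11.9, from 2000 variable genes, 30 principal components, 15 neighbours and a resolution of 0.5, with no correction for plate. Markers of each cell type were fixed in advance, and a marker was counted where at least 25% of a cluster's cells held it and its mean CPM, with 10 added, was at least 2 times that of the other cells. That at least 4 markers were needed to name a cluster was set after the counts were seen. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for TMM factors. The grouping, the rule, the cell filter, the gene lists and most alternatives were set before the data were examined. These alternatives were other cell filters, minimums of expression, pseudocounts, weights of plates and cells, scalings, equal depth, exclusion of cells with markers of other types, leaving out each plate, and batch 3 alone. Added later were cells of at least 500 genes, cells of 1000 to 1700 genes, detection in at least 30% of cells, 5 cells per plate, and exclusion of cells with Xist reads.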

Results

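Skeletal stem cells, the cells that give rise to bone, cartilage and stroma, were sorted from mouse long bones by flow cytometry and profiled cell by cell with SmartSeq2, a full-length RNA sequencing method. The 670 wells lay on 7 plates, each of 95 or 96 wells, with 1 plate of postnatal day 3, 3 plates of 2 months and 3 plates of 24 months. All wells are labelled male. The labels name no animals, so each age counts as 1 sample, no p-value is given, and the spread between plates of an age is given as a description. A cell was used when it held at least 1000 genes, at least 50000 gene reads and under 20% mitochondrially encoded reads.

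The ages differed first in how many wells gave a usable cell. At postnatal day 3, 68 of 95 wells passed (71.6%, exact 95% interval 61.4% to 80.4%). At 2 months 53.7% of wells passed (47.7% to 59.5%), with 15, 70 and 69 cells on plates 1, 3 and 4. At 24 months 15 wells passed (5.21%, 2.94% to 8.44%), with 5 on each of plates 2, 5 and 12. Detection of a gene is given below as a share of the passing cells of an age. Spike-in reads come from RNA added to the wells, and whether all plates got the same amount was not checked. They took a median of 95.1% to 98.9% of the reads in wells of the 24-month plates and 76% on plate 1, against 5.88% to 11.5% on the other plates. Passing cells held 62919 to 3563660 gene reads at 2 months, 93214 to 2246142 at postnatal day 3 and 1131874 to 5994911 at 24 months. Intervals and limits here cover counting error only, since reads made by PCR are not independent molecules and cells of an age are not independent animals.

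**Figure D1:**
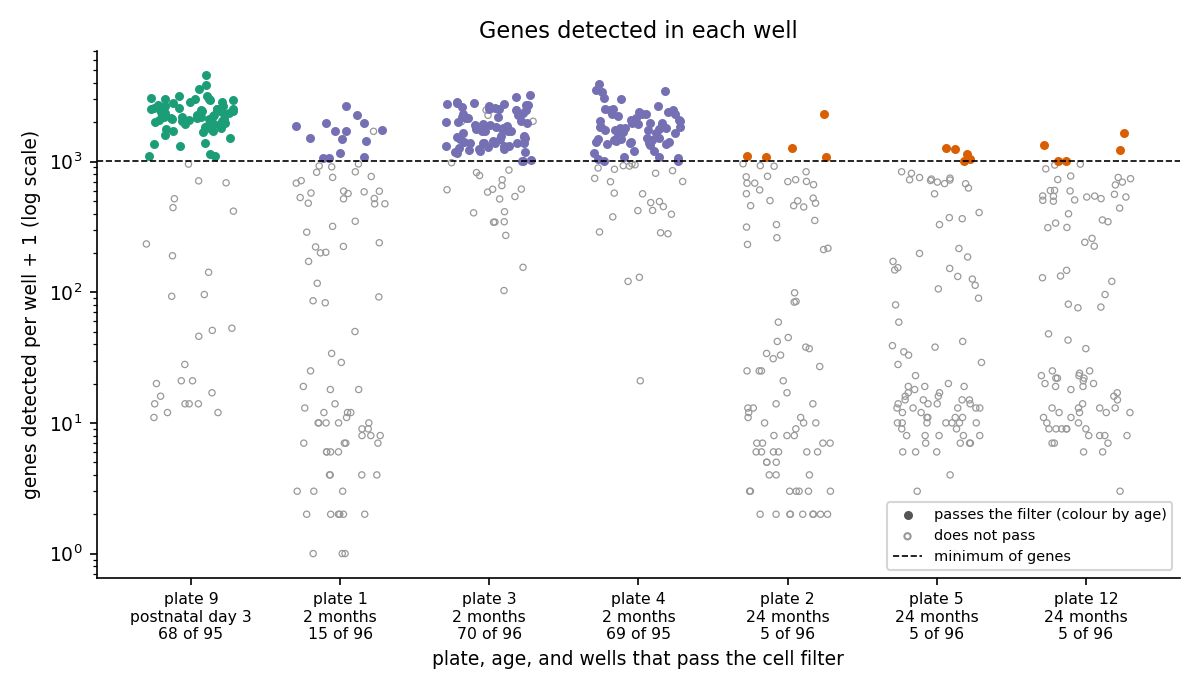
Genes detected in each of the 670 wells, by plate, on a log scale with 1 added. Filled points are wells that pass the cell filter, coloured by age, open points are wells that do not, and the dashed line marks the minimum of 1000 genes. The 24-month plates hold 5 passing cells each, against 15 to 70 on the plates of the other ages.

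At equal depth, fewer genes were detected in cells of the older mice. After each cell was thinned to 50000 reads, the median number of genes was 1750.5 on the postnatal day 3 plate. It averaged 1225 over the 2-month plates (SD 98.8, n = 3 plates) and 850.7 over the 24-month plates (SD 73, n = 3 plates). The highest 24-month plate, at 932 genes, lay below the lowest 2-month plate, at 1111. When a gene needed at least 2 counts the plates overlapped, with 2-month plate 1 at 709 genes and the 24-month plates at 736, 748 and 857. Cell cycle genes were rare at all ages. At least 4 of the 20 listed genes were detected in 9 of 68 cells at postnatal day 3 (13.2%, 6.23% to 23.6%), in 8 cells at 2 months (5.19%, 2.27% to 9.98%) and in 0 of 15 at 24 months, which allows a share of up to 20%. The median correlation between cells of a plate (Spearman's rho across 1000 genes, which are not independent) was 0.296 at postnatal day 3. It was 0.197 at 2 months, with plates from 0.094 to 0.25, and 0.209 at 24 months, with plates from 0.136 to 0.254, so the adult ages overlapped. At 200000 reads they did not, with 24-month plates at 0.142, 0.249 and 0.256 and 2-month plates from 0.257 to 0.26. Unsupervised clustering gave 5 clusters. Cluster 1 (11 cells) carried 6 of 8 osteoblast markers, and cluster 5 (15 cells, all on the single plate of postnatal day 3) carried 4 of 8 fibroblast markers. The other clusters met no marker rule and stay unnamed. The ages lay largely in different clusters: of the 15 cells of 24 months, 6 lay in cluster 1 (4 of them on plate 5), 7 in cluster 2 and 2 in cluster 3, which held 76% of the cells of 2 months, and 44 of the 68 cells of postnatal day 3 lay in cluster 4. Genes that define the clusters also differ between ages, so these numbers are not read as shares of cell types, and the folds below compare different mixtures of cells.

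The comparison of 24 with 2 months asks what changes in these cells with age, the subject of the series. Cartilage transcripts were far lower at 24 months, in cells that also lay in other clusters than most cells of 2 months. Cnmd, which encodes the cartilage glycoprotein chondromodulin, averaged 5797 CPM (counts scaled to the same total on each plate) on the 2-month plates and was detected in 68.2% of the cells (60.2% to 75.5%), whereas none of the 15 cells of 24 months held a read of it. The collagen IX genes Col9a1 and Col9a2, whose products coat the fibrils of cartilage, and Matn3, a cartilage matrilin, stood at 3327, 2262 and 3279 CPM at 2 months and at 0 reads at 24 months. Acan, the gene of the proteoglycan aggrecan, was at 1545 against 65.1 CPM and was detected in 1 of 15 aged cells. Sox9, the master transcription factor of chondrocytes, was at 1240 CPM at 2 months (plates 616 to 2335) and 209.01 CPM at 24 months (plates 120.3 to 298), a log2 fold of -2.56.

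Of the 20 cartilage genes, all measured, 14 were lower at 24 months by the size rule and 0 were higher, with a median log2 fold of -4.45 (-4.87 with the 8 genes at 0 reads placed at their bound). That median lay below all of 10000 random lists of the same size and expression, and outside the range of -0.85 to 0.60 found in 20 simulations with no difference between ages. Without plate 5 it was -7.21. In the GENCODE annotation of GRCm38, Cnmd lies on chromosome 14 from 79637690 to 79662170, Col9a1 on chromosome 1 from 24177610 to 24252684, Acan's regulator Sox9 on chromosome 11 from 112782224 to 112787760, and Matn3 on chromosome 12 from 8947929 to 8972028.

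Genes of the immediate early and heat shock response were also lower at 24 months. Of 19 listed genes, 10 were lower and 0 higher (median log2 fold -3.19, percentile 0.00, simulated range -0.73 to 0.44). The 24-month plates differed among themselves in this list by up to 6.88 (plate 2 against plate 5), a spread the simulations do not hold. Each of them lay below each 2-month plate, by -8.67 to -1.71, and the median was -4.72 without plate 2. Junb, an immediate early transcription factor, was at 4043 CPM at 2 months and 138.1 at 24 months. Egr1, another, was at 1558 against 4.41 CPM and was detected in 68.8% of cells (60.9% to 76%) against 2 of 15, and Nr4a1, an orphan nuclear receptor induced in the same way, stood at 772 against 1.88 CPM. Dnajb1, a co-chaperone of heat shock protein 70, was at 1504 CPM at 2 months and at 0 reads at 24 months. Such genes also respond to tissue digestion and sorting.

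Growth-associated genes went the same way. Of 8 measured genes of the insulin-like growth factor and fetal growth list, 5 were lower and 0 higher (median log2 fold -4.62, or -6.49 with genes at 0 reads at their bound, percentile 2.24, simulated range -2.17 to 1.07). Plates of 1 age differed in this list by up to 2.78 at 2 months and 3.46 at 24 months, beyond the simulated range. The percentile was 9.1 without plate 2, 8.34 without plate 5 and 5.17 without plate 4, and in cells of 1000 to 1700 genes 2 of 10 were lower (median -3.68, percentile 11.9). The imprinted gene Peg3 was at 455 CPM and H19, an imprinted RNA, at 54.4 CPM at 2 months, and both had 0 reads at 24 months. Other genes with the lowest folds were Thbs1 (thrombospondin 1, 1165 CPM at 2 months and 2 reads in all at 24 months), Slc44a2, a choline transporter-like gene, at 682 CPM against 0 reads, and Serpina1d at 1077 CPM against 0 reads. Serpina1d shares reads with near-identical copies and is uncertain.

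Fewer genes were higher at 24 months. Ebf1, a transcription factor of B cells and marrow stromal cells, had the highest fold among genes that met the size rule and the limits for naming, with 2375 CPM at 24 months (plates 1069 to 4759) and 18.6 at 2 months, in 7 of 15 cells against 7.79% of cells. Serping1, the inhibitor of complement C1, was at 3793 against 92.1 CPM and was detected in 10 of 15 (66.7%, 38.4% to 88.2%) against 8.44% of cells (4.57% to 14%). The secreted matrix protein gene Ecm1 was at 1746 against 34.1 CPM, and Medag, an adipogenesis-associated gene, at 539 against 6.97 CPM. Cbfa2t2 (1211 against 24.7 CPM), Ccdc3 (493 against 8.18), Sgcb, a sarcoglycan gene (490 against 12.4), and S1pr1, a receptor for sphingosine 1-phosphate (40.7 against 0.11), completed the 8 highest folds, although the fold of S1pr1 became -0.026 with cells of at least 500 genes. H2-D1, a class I antigen presentation gene whose reads overlap with those of its relatives, was at 4708 against 688 CPM and was detected in 13 of 15 cells against 36.4% of cells (28.8% to 44.5%).

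Csf1, the factor that drives macrophage and osteoclast formation, was higher at 24 months, with 144.4 CPM (plates 89.7 to 214.3) against 29.9 CPM (plates 0.05 to 70.2), in 4 of 15 cells against 5.84% of cells (2.71% to 10.8%). Its log2 fold was 2.23, and 3.75 without plate 4. With no cell filter (2.57) and with cells of at least 500 genes (2.24) it no longer met the rule. Of the other genes fixed in advance, Sox9 met the size rule as lower (given above) and the rest did not. Runx2, the osteoblast transcription factor, was at 698 against 123.5 CPM. Cxcl12, the marrow niche chemokine, was at 7857 against 56.8 CPM, but the 24-month plates stood at 19961, 3611 and 0. Lepr, the leptin receptor of marrow stroma, was at 101.1 against 5.70 CPM, Cd200 at 703 against 278.1, Itgav at 49.9 against 18.9, and the osteoclast inhibitor Tnfrsf11b at 323 against 371. The osteoclast inducer Tnfsf11 had 1.37 CPM at 2 months and 0 reads at 24 months, and Pparg, the adipocyte regulator, had 0 reads at all ages.

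Of the other lists, the 10 measured marrow niche factors had a median log2 fold of 4.05 (1 higher, Ebf1, and 0 lower), which lay within the simulated range of -6.32 to 4.66 and became 2.41 without plate 5. The 10 measured interferon and antigen presentation genes had a median of 1.91 (1 higher, H2-D1, 0 lower, percentile 99.7, simulated range -4.11 to 0.19), which became -0.25 without plate 2. Of 18 osteoblast and bone matrix genes, 0 were higher and 1, the transcription factor Sp7, was lower (median 0.38). Of 19 fibrous matrix genes, 2 were higher and 3 lower (median 0.76, percentile 91.7, simulated range -1.18 to 0.61), and pairs of a 24-month and a 2-month plate went both ways (-0.31 to 0.55). The 3 measured tendon and fibroblast markers had a median of 3.08 (0 higher, 0 lower, percentile 97.4, simulated range -5.14 to 1.61). Col5a1, a collagen V chain, was at 534 against 58.5 CPM. The inflammatory and secretory senescence list had 1 higher (Csf1) and 2 lower (Nfkbia and Cxcl1) of 10 (median -0.46, percentile 42.2). Cell cycle genes had 5 lower of 19 (median -3.29, or -6.98 at the bound, percentile 5.64), within the simulated range of -3.83 to 2.03 and of up to 6 lower, and 17 of them had 0 reads at 24 months. Of 12 cell cycle inhibitors and p53 targets, 6 were lower, among them Cdkn1c, at 302 CPM against 0 reads, and Trp53 (median -4.29, or -5.02 at the bound, percentile 6.23, simulated range -3.05 to 1.25 with up to 6 lower).

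By the size rule 2746 genes differed, 2610 of them lower and 4.95% higher at 24 months, of 8804 genes with at least 10 CPM at either age. Without plate 2, 5 or 12 the share higher was 9.84%, 10.4% or 9.65%, and without plate 1 the count was 4571. Plates of the 2 ages separate by chance for 10% of genes in a comparison of 3 with 3. In simulations that drew every cell from the 2-month cells, a mean of 1818 genes (87 higher, 1731 lower, at most 2490) met the rule with no difference present, so most of the count is what the unequal numbers of cells (5 per plate against 15 to 70) give. Among genes detected in at least 30% of cells of the higher age, a limit chosen after the simulation was seen, 379 genes met the rule (26.4% of them higher). The simulated mean was 180.7 (30.8% of them higher), so the balance of directions was close to that with no difference present. The highest simulation reached 73.6% of the real count. For genes higher at 24 months alone, a simulation gave up to 94, close to the real number higher. Every simulation gave fewer genes lower than the real number lower. In those simulations the rule recovered 35.1% of such genes made 4-fold higher and 74.3% of those made 4-fold lower. No batch held both ages, so batch and age cannot be told apart. With a filter of 2000 genes and 200000 reads, 1 cell of 24 months remained, and Csf1, Ebf1, Medag, Ccdc3, Ecm1, Serping1 and Sgcb were then lower than at 2 months.

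**Figure D2:**
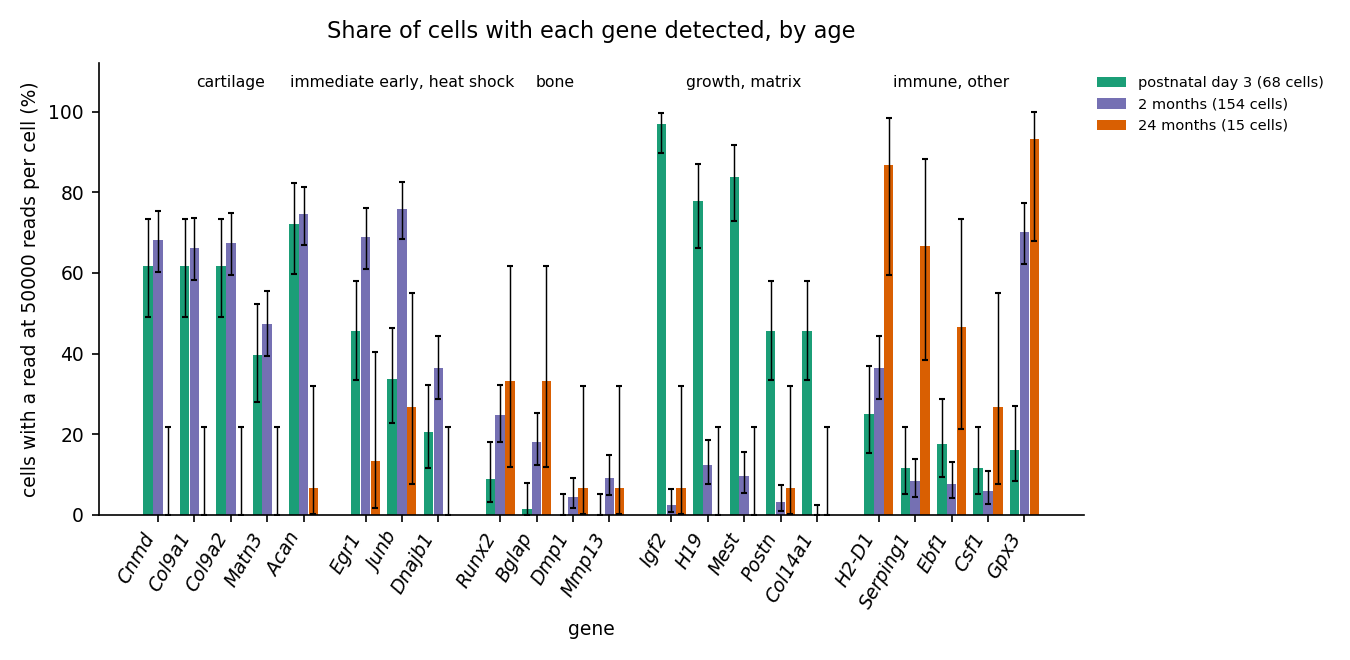
Share of passing cells in which each gene was detected after thinning to 50000 reads, for 68 cells of postnatal day 3, the 15, 70 and 69 cells of the 2-month plates together and 15 cells of 24 months. Bars are shares in percent and lines are exact 95% intervals, which cover counting error only. Cnmd was detected in 68.2% of cells at 2 months and 0 of 15 at 24 months, and Igf2 in 97.1% at postnatal day 3 and 2.60% at 2 months.

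The comparison of postnatal day 3 with 2 months sets growing against adult bone. Fetal growth genes marked the newborn cells. Igf2, the fetal insulin-like growth factor, was at 1937 CPM in 66 of 68 cells (97.1%, 89.8% to 99.6%) at postnatal day 3 and at 3.59 CPM in 4 cells (2.60%, 0.71% to 6.52%) at 2 months. The imprinted genes Mest and H19 were at 4149 against 53.3 CPM and 1246 against 54.4 CPM. All 10 measured genes of that list were higher at postnatal day 3 (median log2 fold 2.89, percentile 100, simulated range -0.57 to 1.16). Igf2 lies on chromosome 7 from 142650766 to 142666816, beside H19, which lies from 142575529 to 142578143.

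Fibrous matrix genes were higher as well, with 13 of 20 higher and 0 lower (median 1.58, percentile 100, simulated range -0.60 to 0.35). In cells of 1000 to 1700 genes, which leaves 9 cells of postnatal day 3, the median was 1.08 (percentile 86.7, 11 higher and 1 lower). Postn, the periosteal matrix protein periostin, was at 2704 against 7.33 CPM. Col14a1, a collagen of dense connective tissue, was at 452 CPM in 31 of 68 cells against 2 reads in all at 2 months, and Aspn, a small proteoglycan, at 310 against 0.07 CPM. The other genes with the highest folds were Mfap4, a microfibril protein (683 CPM against 2 reads in all), Gpc3, a glypican that restrains growth (671 against 0.12 CPM), Kera, the proteoglycan keratocan (339 against 0.12), and Acta2, smooth muscle actin (338 against 0.06).

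Bone matrix genes were lower at postnatal day 3. Of 18 osteoblast and bone matrix genes, 10 were lower and 2 higher (median -3.63, percentile 0.00, simulated range -1.26 to 0.89). The 2-month plates differed among themselves by up to 1.62 in this list, a spread the simulations do not hold. The plate of postnatal day 3 lay -3.18 to -1.18 from them, so its nearest pair lies within that spread. Bglap and Bglap2, which encode osteocalcin and share reads, were at 4.35 against 535 CPM and 1.498 against 483 CPM. Dmp1, an osteocyte matrix gene, was at 0 reads against 250 CPM, and Runx2 at 23.6 against 123.5 CPM. The collagenase gene Mmp13 was at 0 reads against 460 CPM. Tnfrsf11b was at 17.8 against 371 CPM, and Cd200 at 38.3 against 278.1 CPM. The cartilage list as a whole was not apart (2 higher, 5 lower of 20, median -0.17, percentile 22.3), although Sox9 was lower at 381 against 1240 CPM. Csf1 (36.3 against 29.9 CPM), Tnfsf11 (7.26 against 1.37), Itgav (7.12 against 18.9) and Lepr (0 reads against 5.70 CPM) did not meet the rule. Cxcl12 met it as higher, at 229.1 against 56.8 CPM, and turned lower when cells of at least 500 genes were used (log2 fold -1.40).

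The immediate early and heat shock genes were again highest at 2 months, with 13 of 19 lower at postnatal day 3 and 0 higher (median -3.34, percentile 0.00, simulated range -0.45 to 0.34). Hspa1a, a heat shock protein 70 gene, was at 28.6 against 2075 CPM, and Dusp1, a phosphatase induced early, at 206.2 against 7552 CPM. Other genes with the lowest folds were Serpina1d and Serpina1b (both 0 reads, against 1077 and 283.3 CPM, and uncertain for shared reads), Rasd1 (0 reads against 568 CPM), a dexamethasone-induced gene, Stat5a (0.66 against 202.8), Tgm2, a transglutaminase (0 reads against 119.4 CPM), and Per1, a clock gene that glucocorticoids also induce (0.41 against 144.7). Mitochondrially encoded genes were lower for 9 of 13 (median -1.14, percentile 0.90, simulated range -1.08 to 1.33), interferon and antigen presentation genes for 3 of 11, with 1 higher (median -1.88, percentile 0.55), and adipogenic genes for 3 of 8, with 2 higher (median -1.57, or -2.19 at the bound, percentile 0.82). In the interferon list the 2-month plates differed among themselves by up to 3.16, more than any of them from postnatal day 3 (-1.66 to -0.47). The adipogenic median became -0.92 (percentile 6.28) without plate 3 and -0.53 (percentile 11.1) with members of at least 20 CPM. Of 14 Wnt pathway genes, 7 were higher, among them the secreted inhibitors Sfrp1 and Sfrp2, and 1 lower (median 1.49, percentile 99.9). The median became 0.97 without plate 1 and 3.18 without plate 4. In cells of 1000 to 1700 genes it was -2.17, where the median of all genes with at least 10 CPM was -2.95.

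Markers of tendon and fibroblasts moved with the fibrous matrix genes. Mfap4, Kera, Col14a1, Sfrp2 and Tnmd were among the top genes of cluster 5, which holds 15 of the 68 cells of postnatal day 3 and 0 cells of the other ages. How much of these differences lies in those 15 cells was not tested. Of 5 measured, 4 were higher at postnatal day 3, among them Tnmd, a tendon gene (8 of 68 cells against 1 cell at 2 months), and Cd34 (387 against 1.69 CPM). Of 3 pericyte and smooth muscle markers, 2 were higher. By the size rule 3640 genes differed, 2676 higher and 964 lower at postnatal day 3, of 9656 tested. Without plate 1, 1848 were lower and 2388 higher, and in cells of 1000 to 1700 genes 1613 were lower and 1974 higher. With 1 plate against 3, plates separate by chance for 50% of genes, and simulations with no difference gave a mean of 2983 (2092 higher, 891 lower, at most 3623). Among genes detected in at least 30% of cells of the higher age, 692 met the rule (436 of them higher) against a simulated mean of 156.7, and the highest simulation reached 37% of the real count, and 91.9% of such genes made 4-fold higher were recovered. Batch and age cannot be told apart here either, and postnatal day 3 has 1 plate.

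The comparison of 24 months with postnatal day 3 spans the whole age range. Bone genes were higher in the aged cells, most of all on plate 5. Of 17 osteoblast and bone matrix genes, 8 were higher and 1 lower (median log2 fold 2.82, percentile 100, simulated range -1.58 to 1.33). Plate 5 alone had a median of 3.93 against 0.39 and 0.68 on plates 2 and 12, and without plate 5 the median was 1.58, with 7 higher and 3 lower of 16. Bglap2 and Bglap were at 1462 and 1070 CPM at 24 months against 1.498 and 4.35 CPM, and Runx2 at 698 against 23.6 CPM. Cartilage and growth genes were lower. Of 20 cartilage genes 14 were lower and 2 higher (median -4.94, or -5.12 at the bound, percentile 0.00, and -8.40 without plate 5), with Cnmd, Col9a1, Col9a2 and Matn3 at 3754, 3342, 2099 and 1893 CPM at postnatal day 3 and 0 reads at 24 months. Of 10 fetal growth genes 8 were lower and 0 higher (median -7.51, or -8.5 at the bound, percentile 0.00), with Mest at 4149 CPM and Peg3 at 1862 CPM against 0 reads.

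Gpx3, a secreted glutathione peroxidase, was at 12062 CPM at 24 months (plates 4517 to 23095, 14 of 15 cells) against 165.1 CPM in 11 of 68 cells at postnatal day 3, with 1284 CPM at 2 months between them. Lifr, the receptor of leukemia inhibitory factor, was at 5825 against 67.1 CPM, and Lrp4, a receptor that binds sclerostin, at 236.6 against 1.46 CPM. Ric1 was at 153.7 against 0.72 CPM, and Srgn, the proteoglycan serglycin, at 210.02 CPM against 0 reads. Csf1 was higher at 144.4 against 36.3 CPM and Cd200 at 703 against 38.3 CPM. Interferon and antigen presentation genes had a median of 3.37, or 3.74 at the bound (2 higher, H2-D1 and B2m, and 1 lower of 9, percentile 99.98, simulated range -4.05 to 0.77), with 4.48, 3.47 and -0.50 on plates 2, 5 and 12. The lowest folds included Capn6, a calpain of embryonic muscle (1818 CPM against 0 reads), and Tgfbi, a matrix protein induced by TGF-beta (1608 CPM against 0 reads). Cxcl12, Lepr, Itgav, Tnfsf11, Tnfrsf11b and Sox9 (209.01 against 381 CPM) did not meet the rule.

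Fibrous matrix genes were lower for 12 of 20 and higher for 2 (median -1.77, percentile 0.00, simulated range -0.95 to 0.72). Cell cycle genes were lower for 14 of 18 (median -4.70, or -8.49 at the bound, percentile 0.05, simulated range -3.85 to 4.52), but 16 of them had 0 reads at 24 months, and with cells of at least 500 genes the median was -0.33 (percentile 48.2, 1 higher and 8 lower of 20). Marrow niche factors had a median of 4.14 (1 higher of 10, percentile 100, simulated range -4.47 to 2.89), but the plates went both ways, with 3.55, 2.29 and -2.55 on plates 2, 5 and 12, and the median was 2.93 without plate 2. Adipogenic genes had a median of 2.17 (1 higher and 2 lower of 8, percentile 98.6, simulated range -2.70 to 1.19), which became 1.29 without plate 5. Wnt pathway genes were lower for 8 of 14 (median -2.89, or -4.74 at the bound, percentile 2.28), within the simulated range of -2.95 to 0.60. In cells of 1000 to 1700 genes their median became 1.17, while that of all genes with at least 10 CPM went from -1.94 to 0.38. By the size rule 5093 genes differed, 4858 of them lower and 4.61% higher at 24 months, against a simulated mean of 3728 (3523 of them lower, at most 4426 in all). Without plate 2, 5 or 12 the number higher was 479, 494 or 489, or 7.90% to 8.25%. With no cell filter 17.5% were higher, and with cells of at least 500 genes 14.6%. Plates separate by chance for 50% of genes. Among genes detected in at least 30% of cells of the higher age, 920 met the rule (737 of them lower and 19.9% higher), against a simulated mean of 351 (34.4% of them higher, at most 589 in all). A simulation gave up to 310 genes higher, more than the real number higher, and up to 338 lower. At this limit only the number lower thus lay beyond the simulations. Batch 3 held postnatal day 3 and 2 plates of 24 months, and within it 5989 genes differed, 494 higher and 5495 lower. With 1 plate against 2, plates separate by chance for 66.7% of genes, and simulations with no difference gave a mean of 4741 (525 higher, 4217 lower, at most 5450). Csf1, Runx2 and Ric1 turned lower with the filter of 2000 genes, which leaves 1 cell of 24 months.

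**Figure D3:**
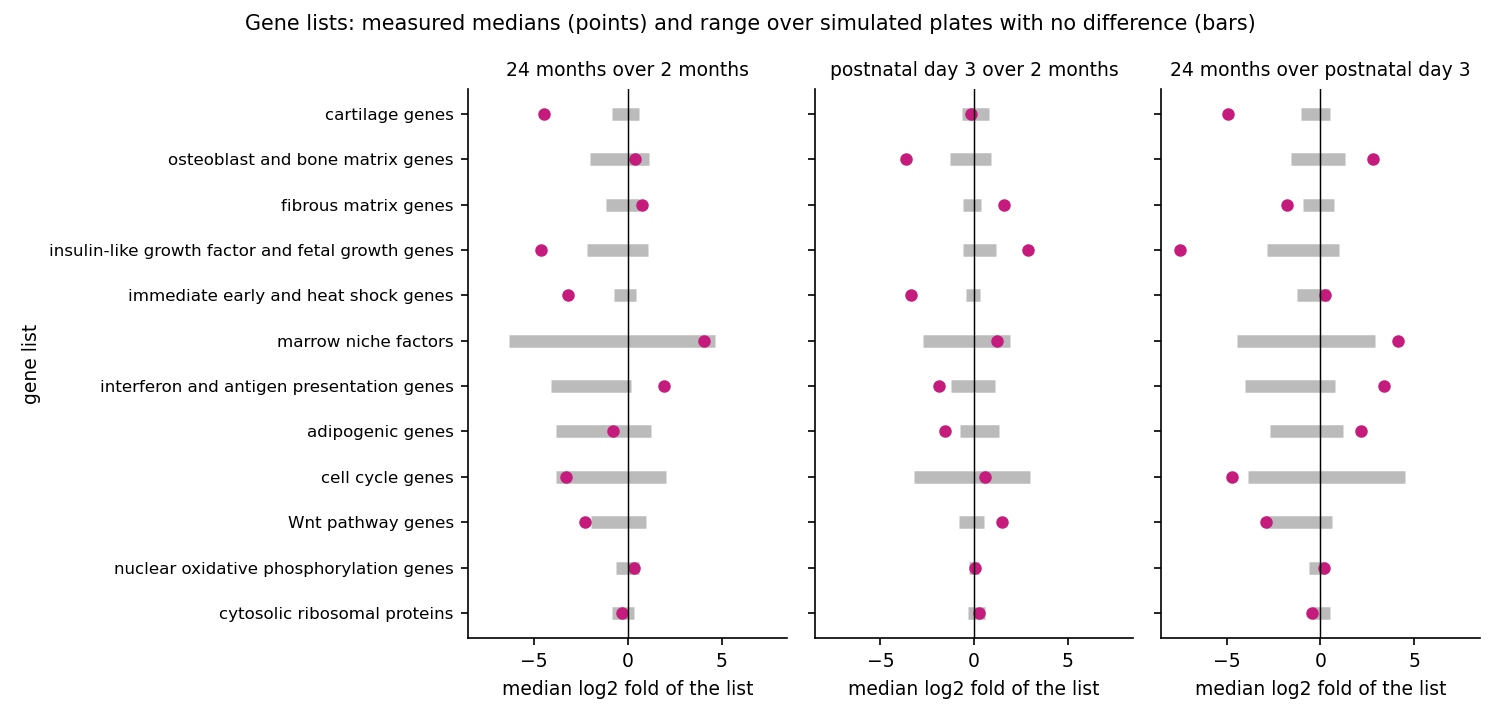
Median log2 fold of 12 gene lists in each comparison of ages (points), with the range of the same median over up to 20 simulations in which the ages do not differ (grey bars). The cartilage list stands at -4.45 for 24 over 2 months, against a simulated range of -0.85 to 0.60, and the fetal growth list at 2.89 for postnatal day 3 over 2 months.

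The medians of several fixed lists lay within their simulated ranges, with 1 exception. Cytosolic ribosomal protein genes had medians of -0.32, 0.24 and -0.43 for 24 over 2 months, postnatal day 3 over 2 months and 24 months over postnatal day 3. In the last, 28 of 84 were lower and 1 higher, where a simulation gave at most 18 lower. Nuclear oxidative phosphorylation genes had medians of 0.32, 0.07 and 0.17 (percentiles 98.7, 22.1 and 99.1), and the first and last changed sign with another scaling. Sirtuin genes had medians of -2.73, 0.84 and -3.45 (the last -5.32 at the bound), BMP pathway genes -1.97, -0.50 and -2.22 (-2.77), and hedgehog pathway genes -1.69 (-1.95), -0.77 and -0.58, all at percentiles between 5.09 and 86.4. Osteoclast regulators had medians of -0.20, 1.04 and -3.05 (-6.70) over 3 to 6 measured genes. The exception was the BMP list for 24 months over postnatal day 3, where 7 of 14 were lower, as many as in a simulation, but the lowest simulated median was -1.73. There, 4 of 6 sirtuin genes were lower, also as many as in a simulation.

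Transcripts of the sorting antigens and of other cell types were checked in the passing cells. Skeletal stem cells are usually sorted as positive for integrin alpha V and CD200 and negative for Thy1, 6C3, CD105, CD45 and Tie2, while the labels name no antibodies. Cd200 was detected in 40 cells at 2 months (26%, 19.2% to 33.6%), 7 of 15 at 24 months and 11 of 68 at postnatal day 3, and Itgav in 12, 3 and 8 cells. Thy1 and Tek were detected in 0 cells after thinning, Eng in 1 cell of 2 months and 1 of postnatal day 3, Enpep, the gene of 6C3, in 1 cell of postnatal day 3, and Ptprc, the gene of CD45, in 3 cells at 2 months and 0 at the other ages. Of the lists of other cells, no myeloid marker reached 5 CPM at any age and endothelial and B lineage markers had at most 1 measured gene. Erythroid and Schwann cell markers had up to 3 measured genes, and pericyte and smooth muscle markers up to 4. Osteoclast, skeletal muscle and megakaryocyte markers had up to 2. Passing cells of 2 months held 6608 reads of Ighm, a B lineage marker, and 10027 of the pan-leukocyte marker Arhgdib. Of 4 pan-leukocyte markers measured at 2 months, 2 (Arhgdib and Lcp1) were lower at 24 months.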

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

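The test of depth for the genes per cell was chosen after its result was seen, and the other tests in this part before. The settings of 500 genes and of 1000 to 1700 genes that they use were added after the first comparison of ages, and the level in wells left out was looked at only afterwards.

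Wells that gave no usable cell still held strong signals of blood cells, which is why they are listed here. In the 24-month wells of plate 2 that did not pass, Ngp, a neutrophil granule gene, stood at 11919 CPM, against a limit of 0.0777 CPM that a count of 0 allows there. It came to 460486 reads in 5 of 91 wells, of which 423760 lay in 1 well. S100a9, a neutrophil calcium-binding protein gene, stood at 2399 CPM in the same wells. In the 24-month wells of plate 12 that did not pass, Hba-a2, a hemoglobin chain of red blood cells, stood at 6373 CPM, against a limit of 0.115 CPM, with 166716 reads in 3 of 91 wells and 165203 of them in 1 well. Hba-a2 shares reads with Hba-a1, which stood at 4010 CPM. Neither Ngp nor Hba-a2 had a read in the 15 passing cells of 24 months. Such signals were not particular to that age: in the wells of 2-month plate 1 that did not pass, the hemoglobin gene Hbb-bs stood at 1486 CPM, S100a8 at 704 and Hba-a1 at 697, and passing cells of 2 months held 4780 reads of Hba-a2. A sort against CD45 and against red cells would remove both kinds of cell, and the labels name no antibodies.

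Fewer genes were detected per cell at 24 months among cells that pass the filter. Lower depth argues poorly for it, since the 24-month cells hold more gene reads and, after thinning to 50000 reads, the highest 24-month plate median was 932 genes against 1111 on the lowest 2-month plate. With at least 2 counts per gene the plates of the ages overlapped, so their separation does not hold at that setting. Less cellular RNA relative to spike-in reads is argued against as the whole cause only if all plates got the same amount of spike-in RNA, which was not checked. On plates 3 and 4 of 2 months the ratios of gene to spike-in reads, 13.1 and 9.92, lay below those of the 24-month plates (14.5, 15.1 and 38.04). Plate 1 of 2 months stood at 142.9, above all of them, so this explanation stays open for that plate. The ratio thus differed widely between plates of 1 age. The ratio covers passing cells only, and damage to cells before sorting, batch and age itself stay open and were not tested.

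Cartilage genes were lower at 24 months. Fewer detected genes per cell are argued against as the whole cause, since the list's median log2 fold was -4.43 in cells of 1000 to 1700 genes at both ages. The few cells left by the filter are also argued against, since the median was -4.25 with cells of at least 500 genes. At that setting Cnmd was detected in 1 of 65 cells of 24 months (1.54%, 0.0389% to 8.28%) against 58.2% of 2-month cells (50.7% to 65.4%), and Col9a1 in 0 of 65 against 57.6%. A difference between batches stays open, since no batch holds both ages. The plates of 2 months, each from its own batch, differed by at most 0.31 in the list's median, and pairs of 24-month plates by -1.21 to 2.17. Every pair of a 24-month and a 2-month plate differed by -10.15 to -3.48. The 24-month plates lay -9.50 to -4.97 from the plate of postnatal day 3, with which 2 of them share batch 3. That plate lay only -0.41 to -0.03 from the 2-month plates, which argues against batch 3 itself lowering these genes, as far as newborn and 2-month cells would otherwise be alike, and plate 5 is alone in its batch. A change with age, such as a smaller part of cartilage-forming cells among those sorted, may therefore explain it, as may a change in dissection or sorting that went with age.

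Of the 10 ways to split the 6 plates of 2 and 24 months into 3 and 3, the real split gave 2746 genes and was the only 1 to give as many. The highest other split gave 1032. The test says nothing about age, since the real split alone puts all plates of 5 cells on 1 side, and simulations with no difference at these cell numbers gave a mean of 1818 genes. The 10 splits are also too few for a share under 0.05.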

How the results depend on the processing

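Cells of at least 500 genes, cells of 1000 to 1700 genes, detection in at least 30% of cells, 5 cells per plate and exclusion of cells with Xist reads were chosen after the first results were seen. No paired analysis was possible because the labels name no animals and the replicate numbers only name cells.

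The count of genes that differ between 24 and 2 months (2746) moved to 6713 with at least 2000 genes and 200000 counts, which leaves 1 cell of 24 months. It moved to 1295 in cells of 1000 to 1700 genes, where the cause was not tested, to 1176 at 50 CPM and to 379 with detection in at least 30% of cells, where fewer genes are tested. With 5 cells per plate, which takes most cells from 2 months, it was 602, of which 36.2% were higher at 24 months against 4.95% before. Plates of 3 against 3 separate by chance for 10% of genes. No simulation was made with 5 cells on every plate, so an excess of these 602 genes over chance was not tested. Leaving out 1 plate gave 2734 to 4571, the highest without plate 1, the 2-month plate with the fewest cells. For postnatal day 3 against 2 months (3640) the count moved to 1792 at 50 CPM and 692 with detection in 30% of cells. For 24 months against postnatal day 3 (5093) it moved to 7865 with the strict filter, 2632 in cells of 1000 to 1700 genes, 1992 at 50 CPM, 920 with detection in 30% of cells and 2946.5 with 5 cells per plate. The other alternatives kept these totals within 1.5 times, among them no cell filter (1998 for 24 against 2 months, 19.1% of them higher). For 24 against 2 months, TMM scaling changed the log2 folds by a median of -0.18, and the median fold of genes with at least 10 CPM went from -1.56 to -1.92.

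Some directions reversed. The interferon and antigen presentation list of 24 against 2 months ranged from -0.25 to 2.31 when 1 plate was left out, the lowest without plate 2. Oxidative phosphorylation genes became -0.0096 with TMM scaling for 24 against 2 months. Against postnatal day 3 they became -0.070 with the mean of cells' CPM, -0.38 in cells of 1000 to 1700 genes and -0.011 with TMM scaling, and ranged from -0.052 to 0.48 without 1 plate, the lowest without plate 12. In cells of 1000 to 1700 genes the Wnt list became -2.17 for postnatal day 3 against 2 months and 1.17 for 24 months against postnatal day 3. That setting leaves 9 cells of postnatal day 3, and genes as a whole moved the same way. The median fold of genes with at least 10 CPM went from 0.23 to -2.95 and from -1.94 to 0.38, so these 2 reversals are not particular to the Wnt list. The cause was not tested for any of these.

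With the strict filter, and so 1 cell of 24 months, Csf1 became -5.62, Ebf1 -0.93, Medag -3.85, Ccdc3 -0.12, Ecm1 -5.18, Serping1 -2.28 and Sgcb -2.30 for 24 against 2 months, and Csf1 -5.53, Runx2 -4.92 and Ric1 -0.89 against postnatal day 3. S1pr1 became -0.026 for 24 against 2 months with cells of at least 500 genes. Cxcl12 became -1.25 with no filter and -1.40 at 500 genes for postnatal day 3 against 2 months. The cause was not tested.

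The gap in genes per cell between 24 and 2 months was -374 at 50000 reads, -579 at 200000 reads and -199 with at least 2 counts per gene. Cells with at least 8 of 20 cell cycle genes made up 4.41% at postnatal day 3. Clusters numbered 8 at a resolution of 1 and 3 with 1000 variable genes. Of the alternatives for the medians of 28 lists, 54 moved a value by more than its spread without reversing it, 8 reversed it and the rest did neither. Of 1482 alternatives for named genes 360 moved, 13 reversed and 1109 did neither, where only genes that met the rule were counted as reversed. Others also changed sign under some alternative, such as Runx2 (2.49, lowest -7.55) and Cxcl12 (7.09, lowest -5.57) for 24 against 2 months. Of the alternatives for marker shares, 2 moved. Each 24-month cell holds at least 1131874 gene reads, and with 15 cells a gene present in up to 20% of cells can go unseen.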

Other observations

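The clock genes, Prg4, Chad and Apoe below, and all tests of Xist, were chosen after their values were seen.

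Levels of 5 genes of the circadian clock are given here, with no test of the clock as a group, and the labels give no hour of collection. Nr1d1, a repressor of the clock that cycles over the day, stood at 198.2 CPM at 2 months (plates 186.1 to 208.8) in 33.1% of cells (25.8% to 41.2%), at 6.28 CPM in 1 of 68 cells at postnatal day 3 and at 0 reads at 24 months. Bhlhe41, which represses clock activators, was at 205.8 CPM at 2 months, 147.1 at 24 months and 2.69 at postnatal day 3, and its relative Bhlhe40 at 1002, 838 and 94.2 CPM. Dbp, an output gene of the clock, stood at 154.4, 295 and 4.11 CPM, with 2-month plates from 0.10 to 304, which overlap postnatal day 3. Per3, a period gene, was at 803 CPM at 24 months (plates 129.5 to 1384) against 84.6 CPM at 2 months. The 5 genes did not go the same way between 24 and 2 months.

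Levels of 3 other genes are given as single values, with no test of a group. Prg4, which encodes the joint lubricant lubricin, stood at 4367 CPM at 2 months, 3081 at 24 months and 460 at postnatal day 3. Chad, the cartilage adhesion protein chondroadherin, stood at 11032, 1906 and 951 CPM, and Apoe, a lipid carrier, at 3318, 2373 and 95 CPM, with 0 reads on plate 12 of 24 months.

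Xist, the RNA that silences an X chromosome in female cells, had reads in 22 of 68 passing cells of postnatal day 3 (32.4%, 21.5% to 44.8%), although the cells are labelled male, and in 0 cells of the other ages. It came to 3735 reads, with 1 to 885 per cell. Carry-over into most wells of the plate is argued against, since 46 of the 68 cells held 0 Xist reads. The 27 wells of the plate that did not pass also held 0, but they have only 917237 gene reads in all. Carry-over into some wells, such as those with few Xist reads, stays open. Cells of female pups may be the source: 1 of the 22 cells with Xist held a read of a Y-linked gene (4.55%, 0.115% to 22.8%), against 10 of the other 46 (21.7%, 10.9% to 36.4%). These intervals overlap and 36 cells held reads of neither, so the counts are too few to decide, and newborn pups are hard to sex by eye. Without the cells that held Xist, 3953 genes differed between postnatal day 3 and 2 months (3640 with them) and 4957 between 24 months and postnatal day 3 (5093 with them). The medians of the 22 lists compared kept their sign, and that of the osteoblast list for 24 months against postnatal day 3 went from 2.82 to 4.72.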
